A study of Mus musculus with 21 samples.

How the data were processed

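The series holds 21 samples of sorted mouse B cells, each hybridised to 1 Illumina MouseRef-8 v2 bead array: IRA (4), FO (3), MZ (4), T1 (2), Plasma (4) and B1a (4). Per the labels, female C57BL/6 mice of 6 to 8 weeks were used and up to 10 animals were pooled for a sample. The labels give LPS treatment at 0.4 mg/kg intraperitoneally over 4 days for all groups but B1a, which is given as steady state and peritoneal. Cells were sorted straight into lysis buffer, total RNA was extracted and biotin-labelled, and the arrays were run on an Illumina BeadStation. Yields, RNA quality, amplification, hybridisation dates, slides and scanner settings are not given in the sources used here.

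The authors deposited a table of signal intensity per probe and array, which the file headers call non-normalised. Its values were on a linear scale with a lowest value well above 0, so no background had been taken off. Beside each signal the authors deposited a detection p-value per probe, which fell as the signal rose with 1 reversed step over all arrays. How the software computed these p-values is not given in the sources used here, and they were read as Illumina's share of negative control beads at or above the signal. A second table of deposited intensity values, the authors' processed ones, was linear and had the same lowest (-19.2095) and highest (22738.1) value on all 21 arrays with medians of 4.98 to 5.01. By the values alone these had been background-subtracted and quantile-normalised; the method and software are not given in the sources used here. The order of probes within each array was that of the signal table, with rank correlations of at least 0.9999998, which tied the columns of the 2 tables to the same samples.

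Comparisons, tests, gene lists, alternatives and the rule for naming genes were set before the data were examined. In R 4.3.3, signals were background-corrected and quantile-normalised with neqc of limma 3.58.1, using the detection p-values in place of control probes and an offset of 16, and taken to log2. Of the 25697 probes, 23978 had 1 gene symbol in the platform annotation, 23962 of them through an Entrez identifier matched to the current symbol, and 1719 had none. A probe was tested when its detection p was under 0.01 on at least 2 arrays, which 11006 passed. Of these, 633 had no symbol, and 2744 were set aside because another probe of the gene had a higher mean over all arrays, which left 7629 genes.

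The depth of an array is set by signal over background. The arrays detected 5622 to 9183 probes at p under 0.01, 21.9% to 35.7% of all. The lowest level of a probe at detection p under 0.05 was 4.64 to 4.97 on 20 arrays and 5.34 on T1 replicate 1, so folds against levels near there are compressed. The median SD of a gene between arrays of a group was 0.122 in B1a and 0.210 to 0.229 in the other 5 groups. Where a gene's tested probe was above background (detection p under 0.05) on no array of a group, the fold was given as a lower bound, and where this held in both groups no fold was given.

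All 21 arrays entered 1 linear model with 6 groups (limma lmFit, contrasts.fit and eBayes), with 15 residual and 7.12 prior degrees of freedom and no block. The comparisons were IRA against each of the 5 other groups, MZ against FO and Plasma against FO, at a Benjamini-Hochberg adjusted p under 0.05 over all genes of a comparison. A gene counted as set apart from all 5 when it passed in the same direction in each IRA comparison. Similarity was the mean Pearson correlation of the IRA arrays with those of another group. Of 25 gene lists, 21 had at least 5 measured members and were tested with limma's camera at a preset correlation between genes of 0.01, adjusted over 147 tests. The alternative with the correlation estimated from the arrays was run on all of them. The lists covered antibody-secreting cells, the endoplasmic reticulum, B cell identity, MHC class II, B-1, marginal zone and follicular cells, replication, mitosis, adhesion, innate sensing, interferon and NF-kB targets, cytokines, glycolysis, the respiratory chain, sorting antigens, handling stress and markers of other cells. Some genes stood in more than 1 list, so the calls of such lists are not independent. Members were also adjusted over the list alone, and those counts are given where they differed.

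Genes were named by rule. For each IRA comparison these were the 10 largest rises and 10 largest falls among genes that passed and whose arrays did not overlap between the groups, all sorting antigen genes, Csf2, and for each list up to 4 members with the smallest adjusted p. For the genes set apart from all 5, the 15 each way with the largest smallest difference were eligible, and for MZ against FO and Plasma against FO the 5 largest each way. The text names some of the genes eligible under the rule, and says where a gene was chosen after its values were seen.

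Replicate numbers were checked as a possible pairing. Once group means were removed, arrays of different groups with the same number correlated at a mean of 0.00188 (46 pairs) and those with different numbers at -0.000472 (136 pairs), so the numbers were not used as pairs. Alternatives changed 1 choice at a time: offset 50, no background correction, median centring in place of quantile normalisation, the authors' values, 3 other filters, all probes, trended robust variance, each pair of groups fitted alone, array weights, replicate number as a block and each array left out. The real grouping was set against all other splits of the same arrays where both groups had at least 3.

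The steps were tested on simulated data, made of arrays of the same sizes and background with changes added in IRA arrays. Changes were added only to brighter genes, all genes had the same independent noise, and the other groups did not differ. Recovery was therefore not tested for faint genes, for genes of wider spread or for lists of correlated genes. Of 4-fold changes 100% were recovered in all 5 IRA comparisons, of 2-fold changes 92.4% (T1) to 100% (MZ), and of 1.5-fold changes 29.2% (T1) to 55.4% (MZ). Among 7591 unchanged genes, 0 (FO) to 43 (B1a) passed. A list of 20 shifted genes passed in each comparison, and 20 unshifted genes did not. Figures were drawn with Python 3.11.15 and matplotlib 3.10.9.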

Results

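Transcript levels were measured on 21 bead arrays of 25697 probes in 6 sorted mouse B cell populations. IRA cells (innate response activator B cells, n = 4), follicular (FO, n = 3), marginal zone (MZ, n = 4), transitional type 1 (T1, n = 2) and plasma cells (Plasma, n = 4) came from spleens of female C57BL/6 mice 4 days into treatment with lipopolysaccharide (LPS, a bacterial cell wall component) at 0.4 mg/kg, and B1a cells (n = 4) came from the peritoneum of untreated mice. Each sample pooled cells of up to 10 mice. IRA cells were sorted for high VLA-4 and as positive for CD19, MHC class II, CD93, IgM and CD43 but not CD23. B1a cells therefore differed from IRA cells in tissue and in LPS treatment as well as in cell type, and no group other than B1a came from untreated mice.

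The arrays detected between 5622 probes (T1 replicate 1) and 9183 probes (B1a replicate 3) at detection p under 0.01, and 7629 genes were tested. Correlations across genes between arrays of 1 group ran from 0.954 in T1 to 0.997 in B1a; genes are not independent replicates. Plasma and B1a arrays formed a set of their own in the deposited signals. Their lowest signals were 38.4 to 45.2 and their highest 26323.8 to 37187, against 63.5 to 78.3 and 12191.8 to 20088.8 on the 13 arrays of IRA, FO, MZ and T1. Every comparison of IRA with Plasma or B1a crosses these sets of arrays, and so does Plasma with FO, whereas comparisons among IRA, FO, MZ and T1 do not. All levels are log2 intensities after background correction and quantile normalisation, with the SD over the arrays of a group. The p-values are limma's and measure only the spread between samples, which may be technical. The number of arrays limits the precision of each value.

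**Figure D1:**
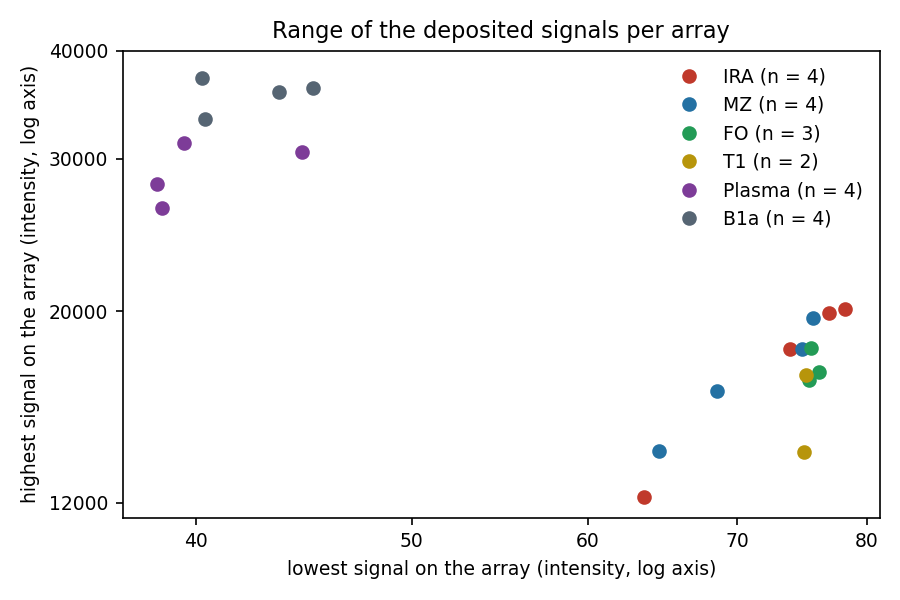
Lowest and highest deposited signal of each of the 21 arrays (arbitrary intensity units, log axes), coloured by group. The 8 arrays of Plasma and B1a lie at minima of 38.4 to 45.2 and maxima of 26323.8 to 37187, apart from the other 13.

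Transcripts of several sorting antigens were measured. Cd93 stood at 7.23 ± 0.06 in Plasma and 5.34 ± 0.42 in IRA cells, where replicate 2 (4.83) lay below the lowest detected level of its array (4.97). Elsewhere Cd93 was at or near background, with B1a replicate 2 at 4.98. Fcer2a, which encodes CD23, was highest in FO (11.13 ± 0.12) and T1 (9.83 ± 0.24), and reached 7.99 ± 0.58 in MZ against 6.16 ± 0.42 in IRA cells. Sdc1, which encodes the CD138 of the Plasma sort, stood at 6.60 ± 0.35 in IRA cells, 5.89 ± 0.47 in Plasma, 5.31 ± 0.22 in MZ and 4.29 ± 0.03 in FO. H2-Ab1 was bright in all 6 groups, from 12.77 in Plasma to 13.90 in FO. Cd5 had its highest group mean in B1a (5.21 ± 0.08), where its transcript was detected on all 4 arrays, out of 5 arrays in all. The T1 arrays were apart in Cd5: IRA minus T1 was -1.3563 without T1 replicate 1 and 0.10499 without T1 replicate 2. Probes of Spn and Itgb1 lay near background, the Itga4 probe was above background on no array, and the probe annotation listed none for Cd19 or Ighm. Differences in these genes between groups sorted by them are no finding.

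By correlation across genes, IRA cells resembled MZ cells most, a group of their own set of arrays. The mean correlation across genes with the IRA arrays was 0.951 ± 0.007 for MZ, 0.910 ± 0.014 for Plasma, 0.901 ± 0.008 for T1, 0.887 ± 0.010 for FO and 0.813 ± 0.010 for B1a (SD over the 4 IRA arrays). MZ cells in turn correlated with FO at 0.943. Principal components 1 and 2 held 43.9% and 29.1% of the variance. Component 1 split the sets of arrays, with Plasma and B1a positive and all other arrays negative. On component 2 the IRA arrays (-34.8 to -23.1) lay within the range of Plasma (-50.2 to -18.8) and apart from MZ (-4.06 to 6.84). Correlation and component 2 thus differ on which group is nearest to IRA. The values for Plasma and B1a were taken across the sets of arrays, so set and cell type cannot be told apart in them.

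**Figure D2:**
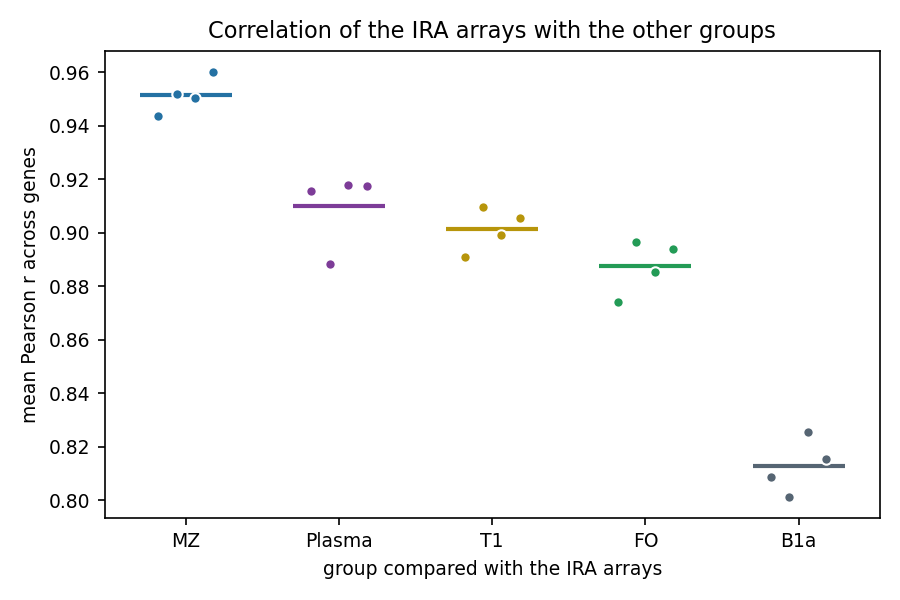
Mean Pearson correlation across the 7629 tested genes of each of the 4 IRA arrays (points) with the arrays of each other group, and the mean over the IRA arrays (bars across). MZ averaged 0.951 and B1a 0.813.

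The comparison with FO cells asks how IRA cells differ from follicular B cells of LPS-treated mice. IRA cells had more transcript of antibody-secreting cell, endoplasmic reticulum, cell cycle and respiratory chain genes, and less of B cell identity, MHC class II and follicular genes. All of these list calls, counted below, are lost with an estimated correlation between genes (adjusted p = 0.183 to 0.340). The largest rises were in Plpp5 (22.1-fold; 10.02 ± 0.17 against 5.55 ± 0.71), the folding enzyme gene Fkbp11 (21.2-fold; 10.91 ± 0.17 against 6.50 ± 0.23) and the protease inhibitor gene Slpi (20.7-fold; 10.21 ± 0.39 against 5.84 ± 0.33). Bhlha15, a transcription factor of secretory cells, was 19.3-fold higher, the calcium channel gene Cacna1h 16.2-fold and Rgcc 19.2-fold. Xbp1, which drives the secretory programme, rose 10.7-fold to 13.02 ± 0.10, and Tnfrsf17, the receptor BCMA, 13.8-fold. Il10 was at least 4.16-fold higher in IRA cells, as it was above background on no FO array (6.95 ± 0.42 against 4.52 ± 0.08, adjusted p = 5.79e-07). Among the largest falls were Sorl1 (11.9-fold lower), Tbc1d10c (11.8-fold) and the germinal centre factor Bcl6 (11.5-fold; 6.15 ± 0.39 against 9.67 ± 0.20).

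Of the antibody-secreting cell genes, 13 of 14 were higher and 1 did not pass, with Mzb1 5.30-fold higher (adjusted p = 4.06e-11, and adjusted p = 0.183 with an estimated correlation). Among the 34 genes of the endoplasmic reticulum, 30 were higher, 1 lower and 3 did not pass (adjusted p = 7.84e-19, and adjusted p = 0.183 with an estimated correlation). Edem1 was 18.4-fold higher, Creld2 17.7-fold, Sel1l 9.90-fold and Spcs1 7.90-fold. Mitosis genes were higher in 14 of 15 cases (15 higher and 0 lower adjusted over the list alone; adjusted p = 2.17e-12, and adjusted p = 0.183 with an estimated correlation), among them Prc1 (6.30-fold), Top2a (5.85-fold) and Cdca3 (5.11-fold). DNA replication genes were higher in 15 of 19 cases (adjusted p = 5.96e-07, and adjusted p = 0.227 with an estimated correlation), with Rrm2 6.55-fold and Tyms 4.37-fold higher. Of the respiratory chain genes 20 of 26 were higher (adjusted p = 9.64e-06, and adjusted p = 0.188 with an estimated correlation), led by Ndufa1 (3.11-fold). B-1 cell genes were higher in 6, lower in 1 and not passing in 6 of 13 cases (adjusted p = 0.0195, and adjusted p = 0.198 with an estimated correlation), with Lgals1 6.41-fold and Cd9 3.72-fold higher. Median centring ended the call of the B-1 list (adjusted p = 0.112).

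B cell identity genes went the other way in IRA cells. Of 20, 17 were lower than in FO, 2 higher and 1 did not pass (2 higher and 18 lower adjusted over the list alone; adjusted p = 2.75e-07, and adjusted p = 0.247 with an estimated correlation). Ciita was 7.19-fold lower, Ets1 4.37-fold and Foxo1 2.49-fold. MHC class II and presentation genes were lower in 11 of 15 cases and 4 did not pass (1 higher and 12 lower adjusted over the list alone; adjusted p = 4.89e-06, and adjusted p = 0.340 with an estimated correlation), with H2-Oa 8.65-fold and H2-DMb1 6.78-fold lower. All 6 follicular genes measured were lower (adjusted p = 2.00e-05, and adjusted p = 0.198 with an estimated correlation), and without Fcer2a, whose product the gate excludes, all 5 (adjusted p = 0.000322, and adjusted p = 0.212 with an estimated correlation), among them Satb1 (7.39-fold), Cxcr5 (4.83-fold) and Cd55 (4.77-fold). NF-kB target genes were lower in 8 of 19 cases (adjusted p = 0.00465, and adjusted p = 0.356 with an estimated correlation), with Cd40 4.59-fold and Cd83 3.65-fold lower. These lists overlap: Cd40 is also in the identity and MHC class II lists. Ciita is in both of those, and Cxcr5 and Cd55 are in the identity and follicular lists. Cytokine transcripts split: Il10 rose, whereas Ltb fell 5.77-fold, Il12a 4.74-fold and Tgfb1 2.89-fold, and the list as a whole did not pass (2 higher, 5 lower, 6 not passing, adjusted p = 0.417). Interferon-stimulated genes split as well, with Isg15 4.45-fold and Isg20 at least 3.34-fold higher and Ifit3 2.39-fold lower. Of that list 3 were higher, 7 lower and 8 of 18 did not pass (adjusted p = 0.594 for the list). In all, 1579 genes were higher and 1640 lower in IRA cells, 656 and 551 of them at least 2-fold. With the estimated correlation between genes none of the 147 list tests passed in any comparison, the lowest adjusted p being 0.0986.

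**Figure D3:**
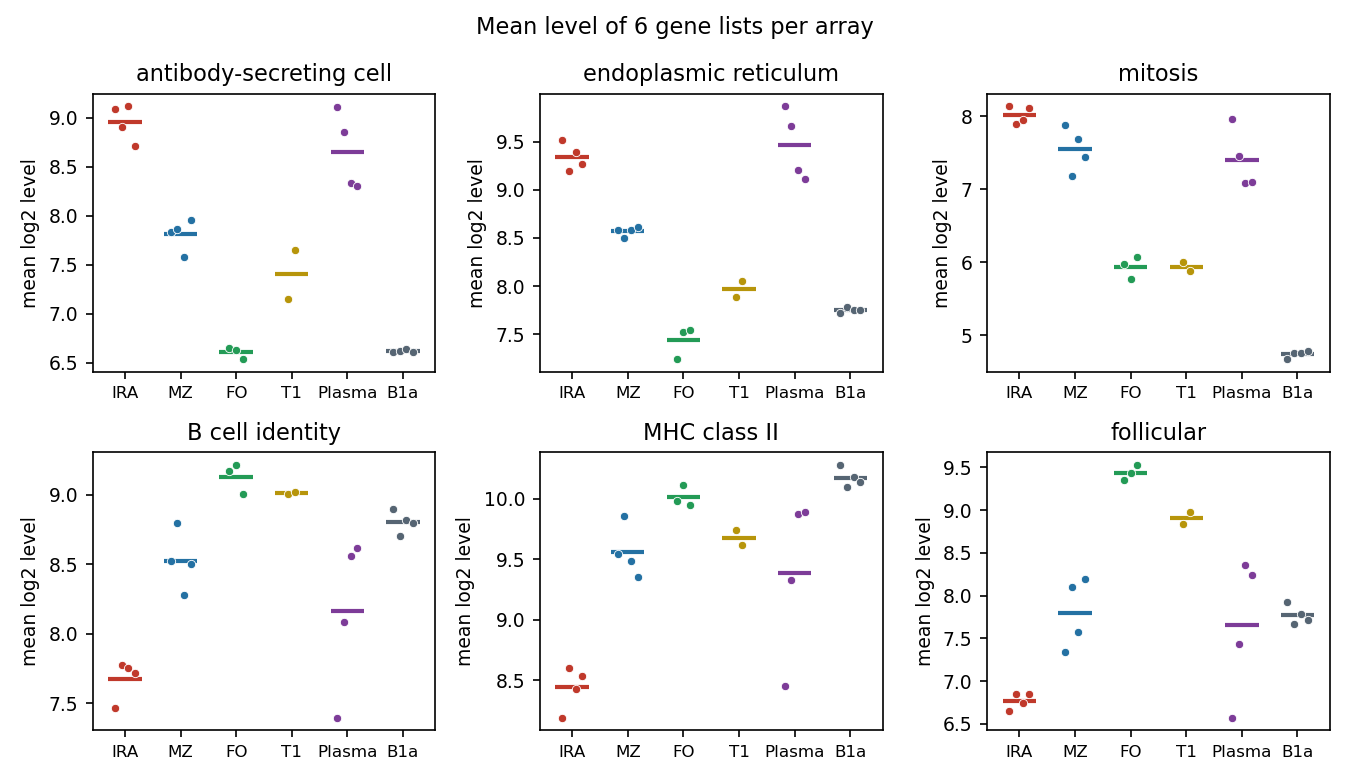
Mean log2 level of the measured genes of 6 lists on each array (points) and the mean per group (bars across). In IRA cells, the antibody-secreting cell, endoplasmic reticulum and mitosis lists lie above FO, and the B cell identity, MHC class II and follicular lists below it.

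IRA and MZ cells were compared next, as MZ was the group nearest to IRA by correlation. Endoplasmic reticulum and antibody-secreting cell genes were higher in IRA than in MZ cells, and marginal zone and MHC class II genes lower. These list calls, counted below, are lost with an estimated correlation (adjusted p = 0.170 to 0.198). Slpi showed the largest rise (7.52-fold; 10.21 ± 0.39 against 7.30 ± 0.36, adjusted p = 1.13e-07). The costimulatory receptor gene Cd28, whose tested probe was above background on no MZ array, was at least 4.53-fold higher (6.99 ± 0.71 against 4.46 ± 0.20), with the survival receptor Tnfrsf17 at 4.81-fold, Tmed6 at 4.42-fold, Socs2 at 4.03-fold and Reln at 4.02-fold. Evi5, Cacna1h and Fut8 were 3.52-fold, 3.46-fold and 3.38-fold higher. The short-chain fatty acid receptor gene Ffar2 had the largest fall (7.94-fold; 6.75 ± 0.47 against 9.74 ± 0.47), then Ell3 (5.88-fold), Asb2 (4.91-fold), Whrn (4.32-fold) and the cannabinoid receptor gene Cnr2 (4.14-fold). Il10, chosen for this comparison after its values were seen, did not separate the pair: it stood at 6.95 ± 0.42 in IRA and 7.18 ± 0.44 in MZ cells (adjusted p = 0.598).

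Marginal zone genes were lower in IRA cells in 9 of 12 cases and 3 did not pass (0 higher and 10 lower adjusted over the list alone; adjusted p = 1.24e-08, and adjusted p = 0.170 with an estimated correlation), among them Dtx1 (4.01-fold), Cd1d1 (2.48-fold) and Fcrl5 (2.91-fold). The antibody-secreting cell genes were higher in 12 of 14 cases (13 higher and 0 lower adjusted over the list alone; adjusted p = 1.56e-10, and adjusted p = 0.183 with an estimated correlation), with Fkbp11 3.03-fold and the joining chain gene Jchain 2.70-fold higher. Endoplasmic reticulum genes were higher in 24 of 34 cases and 10 did not pass (28 higher and 1 lower adjusted over the list alone; adjusted p = 8.54e-15, and adjusted p = 0.183 with an estimated correlation), with Sel1l 2.89-fold and Creld2 2.64-fold higher. MHC class II genes were lower in 11 of 15 cases (adjusted p = 4.48e-09, and adjusted p = 0.198 with an estimated correlation), with H2-DMb2 3.21-fold lower. B cell identity genes were lower in 12 of 20 cases (0 higher and 14 lower adjusted over the list alone; adjusted p = 6.94e-08, and adjusted p = 0.227 with an estimated correlation), among them Cxcr5 (3.42-fold), Cd37 (2.51-fold) and Ets1 (2.19-fold).

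Innate sensing genes were lower than in MZ cells in 9 of 17 cases and 8 did not pass (adjusted p = 0.00179, and adjusted p = 0.198 with an estimated correlation), with Ly86 2.22-fold and Nod1 2.02-fold lower. NF-kB target genes were lower in 5 of 19 cases (adjusted p = 5.49e-05, and adjusted p = 0.198 with an estimated correlation), Cd40 by 3.77-fold and Relb by 2.06-fold. Follicular genes were lower in 3 of 6 cases (0 higher and 4 lower adjusted over the list alone; adjusted p = 0.00188, and adjusted p = 0.346 with an estimated correlation), and in 2 of 5 without Fcer2a (adjusted p = 0.0134, and adjusted p = 0.409 with an estimated correlation). Of the cytokine genes 3 of 13 were lower (adjusted p = 0.0420, and adjusted p = 0.198 with an estimated correlation), with Ltb 3.26-fold lower. Interferon-stimulated genes were lower in 5 and higher in 2 of 18 cases (adjusted p = 0.0420, and adjusted p = 0.513 with an estimated correlation), Gbp2 being 2.44-fold lower and Isg20 1.83-fold higher. Cell cycle differences were small: 3 of 15 mitosis genes were higher (adjusted p = 6.17e-04, and adjusted p = 0.513 with an estimated correlation), with Bub1b at 1.88-fold, and 3 of 19 replication genes (2 higher and 0 lower adjusted over the list alone; adjusted p = 0.194, but 0.0107 without MZ replicate 3). Of the respiratory chain genes 3 of 26 were higher (0 higher and 0 lower adjusted over the list alone; adjusted p = 0.0192, and adjusted p = 0.513 with an estimated correlation), and the call was lost without MZ replicate 2 (adjusted p = 0.102). The cytokine call was lost without IRA replicate 1 or 3 or MZ replicate 1 or 3 (adjusted p = 0.0641, 0.0611, 0.0517 and 0.0785), and the interferon call without IRA replicate 1 or 2 or MZ replicate 1, 2 or 3 (adjusted p = 0.0646, 0.0853, 0.0537, 0.0595 and 0.139) and with median centring (0.0888). Altogether 762 genes were higher and 760 lower in IRA than in MZ cells, 139 and 178 of them at least 2-fold, fewer than in the other IRA comparisons.

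T1 cells share CD93, IgM and the lack of CD23 with IRA cells by the sorting labels and differ in CD43 and VLA-4. The T1 arrays did not follow the label in Fcer2a (9.83 ± 0.24 against 6.16 ± 0.42 in IRA cells), Cd93 was above background on 1 of the 2 T1 arrays (4.66 ± 0.49 against 5.34 ± 0.42), and T1 correlated with FO at 0.953. Against T1, mitosis, replication and secretory genes were higher in IRA cells, and B cell identity and follicular genes lower. These calls, counted below, are lost with an estimated correlation as well (adjusted p = 0.183 to 0.228). The largest rise was in the replication clamp partner gene Pclaf (10.6-fold; 9.30 ± 0.26 against 5.88 ± 0.59, adjusted p = 4.96e-07), then Kdelr2 (9.31-fold), which returns proteins to the endoplasmic reticulum, and Creld2 (8.17-fold). Bcat1 and Sgo1 were above background on no T1 array and were at least 4.21-fold and at least 6.68-fold higher in IRA cells. The mitotic genes Kif18b and Cdc20 rose 7.61-fold and 6.54-fold, and Abcb1b 6.78-fold. B3gnt8 fell 10.8-fold (6.32 ± 0.32 against 9.75 ± 0.43), Tbc1d10c 8.18-fold, Pde2a 7.90-fold, Bcl6 7.28-fold and Sorl1 6.66-fold. Il10 was 3.81-fold higher in IRA than in T1 cells (6.95 ± 0.42 against 5.02 ± 1.01). The 2 T1 arrays were apart in some of these: without replicate 1 the log2 differences of Kdelr2, Abcb1b and Il10 were 2.49, 2.12 and 1.24, and without replicate 2 they were 3.95, 3.47 and 2.68.

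Mitosis genes were higher in 14 of 15 cases (adjusted p = 8.28e-13, and adjusted p = 0.183 with an estimated correlation), among them Prc1 (6.31-fold), Cdk1 (5.53-fold) and Top2a (5.38-fold). DNA replication genes were higher in 17 of 19 cases (18 higher and 0 lower adjusted over the list alone; adjusted p = 2.31e-09, and adjusted p = 0.183 with an estimated correlation), with Tyms 6.30-fold and Fen1 3.04-fold higher. Endoplasmic reticulum genes were higher in 28 of 34 cases (adjusted p = 4.96e-14, and adjusted p = 0.183 with an estimated correlation), Sel1l by 4.60-fold and Pdia3 by 3.55-fold. Antibody-secreting cell genes were higher in 13 of 14 cases (adjusted p = 4.48e-08, and adjusted p = 0.183 with an estimated correlation), with Cd28 at least 3.69-fold, Fkbp11 4.71-fold and Xbp1 3.42-fold higher. Respiratory chain genes were higher in 13 of 26 cases (14 higher and 0 lower adjusted over the list alone; adjusted p = 3.87e-04, and adjusted p = 0.255 with an estimated correlation). Genes of B cell identity were lower in 17, higher in 1 and not passing in 2 of 20 cases (adjusted p = 9.42e-08, and adjusted p = 0.228 with an estimated correlation), Foxo1 by 2.38-fold. MHC class II genes were lower in 13 of 15 cases (adjusted p = 1.03e-05, and adjusted p = 0.356 with an estimated correlation), with H2-DMa 4.38-fold lower. All 6 follicular genes were lower (adjusted p = 7.39e-05, and adjusted p = 0.207 with an estimated correlation), as were the 5 other than Fcer2a (adjusted p = 0.000813, and adjusted p = 0.235 with an estimated correlation), Klf2 by 5.42-fold. Innate sensing genes were lower in 9 and higher in 2 of 17 cases (adjusted p = 0.0111, and adjusted p = 0.284 with an estimated correlation), Irf5 being 2.76-fold and Irak3 3.00-fold lower, a call that median centring ended (adjusted p = 0.170). In total 1460 genes were higher and 1388 lower in IRA than in T1 cells, 652 and 525 of them at least 2-fold. T1 held 2 arrays, and without its replicate 1, which detected the fewest probes, 897 genes were higher. With array weights 891 genes were lower.

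Plasma cells from spleens of LPS-treated mice were the reference for antibody secretion. Secretory genes differed from IRA cells in both directions, and 9 of 15 mitosis genes were higher in IRA cells (adjusted p = 0.662 for that list with an estimated correlation). The 4 Plasma arrays were unlike in B cell transcripts: their mean over the follicular genes ran from 6.57 in replicate 1 to 8.36 in replicate 3, and over the antibody-secreting cell genes from 9.10 in replicate 1 to 8.30 in replicate 4. Sdc1 and other sorting antigens aside, Xbp1 stood at 13.02 ± 0.10 in IRA and 12.81 ± 0.45 in Plasma cells, Tnfrsf17 at 8.93 ± 0.46 and 8.70 ± 0.41, and Bhlha15 at 10.03 ± 0.15 and 9.56 ± 0.47. Slpi was brighter in Plasma (11.69 ± 0.17 against 10.21 ± 0.39) and so was Jchain (2.14-fold lower in IRA cells). Prdm1, the plasma cell regulator Blimp-1, chosen after its values were seen, was 1.60-fold higher in IRA cells (5.50 ± 0.11 against 4.83 ± 0.64, adjusted p = 0.0146), but Plasma replicate 1, at 5.67, lay above every IRA array (highest 5.64), and the next Plasma array was at 4.97. The histone genes H2ac12, H2ac15 and H2ac11 were 6.39-fold, 5.13-fold and 4.98-fold higher in IRA cells, the mitotic gene Cdca8 4.29-fold and the methyltransferase gene Ezh2 4.19-fold. Eprs and Zc3h13 were 5.03-fold and at least 3.31-fold higher, and the shared receptor chain of GM-CSF, Csf2rb, 2.78-fold (6.41 ± 0.51 against 4.94 ± 0.33). Lower in IRA cells were H2-Aa (17.4-fold), the protease gene Ctss (8.23-fold), the actin regulator Evl (8.34-fold) and Paip2 (8.24-fold), and all 4 were similarly bright in B1a.

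Of the endoplasmic reticulum genes 10 were higher, 12 lower and 12 of 34 did not pass (adjusted p = 0.540). Ssr3 was 2.48-fold higher and Sec11c 6.43-fold lower in IRA cells. The antibody-secreting cell genes were higher in 6, lower in 2 and not passing in 6 of 14 cases (adjusted p = 0.309), with Pou2af1 3.06-fold higher. Mitosis genes were higher in 9, lower in 1 and not passing in 5 of 15 cases (10 higher and 1 lower adjusted over the list alone; adjusted p = 0.0146, and adjusted p = 0.662 with an estimated correlation), with Aurka 2.86-fold and Kif23 2.43-fold higher and Tpx2 2.55-fold lower. MHC class II genes were lower in 7 of 15 cases (adjusted p = 0.00161, and adjusted p = 0.555 with an estimated correlation). H2-Eb1 lay at 11.77 ± 0.69 in Plasma against 13.43 ± 0.12 in FO cells, while H2-Aa and Ctss, both of this list, were higher in Plasma and B1a than on all 13 arrays of the other groups. B cell identity genes were lower in 5, higher in 2 and not passing in 13 of 20 cases (1 higher and 5 lower adjusted over the list alone; adjusted p = 0.0305, and adjusted p = 0.673 with an estimated correlation), with Cd22 5.52-fold lower. The B cell identity call was lost without IRA replicate 1, Plasma replicate 3 or Plasma replicate 4 (adjusted p = 0.0825, 0.160 and 0.0949). Without both of these Plasma arrays the identity, MHC class II and mitosis calls were lost (adjusted p = 0.704, 0.175 and 0.194), and the endoplasmic reticulum list passed as lower (adjusted p = 0.00966). Median centring ended the mitosis call too (adjusted p = 0.0564). Sorting antigen genes were lower in 4 and higher in 1 of 9 cases (adjusted p = 0.0305, and adjusted p = 0.183 with an estimated correlation), which the gates select. Counts were 1921 higher and 1507 lower, 304 and 610 of them at least 2-fold (2683 and 1127 with median centring in place of quantile normalisation). Among the 10 largest differences each way, H2-Aa, Ctss, Evl, Paip2, Ptpre, Rps3a1, Pabpc1, Cd53, Uqcrb and Ptma (lower) and Eprs, Ezh2, Fli1, Tob2 and Rock1 (higher) also separated the 8 arrays of Plasma and B1a from the other 13, as 1073 of all 7629 genes did without overlap, and both other Pabpc1 probes went the opposite way. Differences between IRA and Plasma are therefore also differences between the sets of arrays, and set and cell type cannot be told apart here.

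B1a cells, the peritoneal B-1 population, differed most from IRA cells. Most secretory and cell cycle transcripts were lower in B1a than in IRA cells, and most B-1 transcripts higher. These list calls are lost with an estimated correlation (adjusted p = 0.0986 to 0.255). Myl4 was above background on no B1a array and was at least 42.6-fold higher in IRA cells (10.07 ± 0.18 against 4.36 ± 0.06). Plpp5 (37.4-fold), Bhlha15 (37.1-fold), Cacna1h (at least 29.3-fold), H2ac12 (32.1-fold), Rsph1 (at least 23.8-fold) and Vpreb3 (at least 23.7-fold) followed. Tnfrsf17 was at least 19.3-fold higher, as no B1a array detected it, Xbp1 13.2-fold and Il10 4.81-fold. Zcwpw1 had the largest fall (55.1-fold; 4.98 ± 0.30 against 10.76 ± 0.28), then Tubb6 (31.4-fold), Ahnak (27.6-fold), S100a10 (26.8-fold), H2-Aa (22.9-fold), Tsc22d3 (22.7-fold), Diras2 (22.4-fold) and S100a6 (19.6-fold), and Fbxw13 was at least 16.6-fold lower. The IL-5 receptor gene Il5ra was 5.43-fold lower in IRA than in B1a cells.

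B-1 cell genes were lower in IRA cells in 12 of 13 cases (adjusted p = 2.14e-06, and adjusted p = 0.0986 with an estimated correlation), with Anxa2 14.8-fold and Zbtb32 5.25-fold lower. All 14 antibody-secreting cell genes were higher (adjusted p = 7.20e-08, and adjusted p = 0.188 with an estimated correlation), with Fkbp11 10.9-fold higher. Endoplasmic reticulum genes were higher in 25, lower in 1 and not passing in 8 of 34 cases (adjusted p = 6.09e-09, and adjusted p = 0.255 with an estimated correlation), Creld2 by 16.5-fold and Ssr2 by 12.9-fold. Mitosis genes were higher in 14 of 15 cases (adjusted p = 6.44e-11, and adjusted p = 0.183 with an estimated correlation), Top2a by 25.5-fold and Birc5 by 25.2-fold. DNA replication genes were higher in 16 of 19 cases (adjusted p = 1.97e-07, and adjusted p = 0.207 with an estimated correlation), Tyms by 14.6-fold. MHC class II genes were lower in 13 of 15 cases (adjusted p = 5.49e-05, and adjusted p = 0.412 with an estimated correlation), with Ifi30 7.75-fold lower. Genes of B cell identity were lower in 13, higher in 1 and not passing in 6 of 20 cases (adjusted p = 0.00251, and adjusted p = 0.575 with an estimated correlation), with Cd22 8.59-fold lower. Innate sensing genes were lower in 11 and higher in 2 of 17 cases (2 higher and 13 lower adjusted over the list alone; adjusted p = 0.0257, and adjusted p = 0.356 with an estimated correlation), Ly86 being 6.01-fold lower and Ticam1 2.62-fold higher. In this comparison 2291 genes were higher and 2348 lower, 983 and 1072 of them at least 2-fold, but 3651 and 1872 with median centring. Tissue, LPS treatment, cell type and set of arrays all differ between IRA and B1a samples and cannot be told apart. Ptpre was among the largest falls here too (18.6-fold) and separated the sets of arrays, as did H2-Aa, S100a10, Tubb6 and Il5ra.

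Some genes differed in 1 direction between IRA cells and all 5 other populations. In each comparison 270 genes were higher and 79 lower in IRA cells, where independent comparisons would give 2.28 and 1.81 and none of 50 simulations without group effects gave any. The 5 comparisons share the IRA arrays, and neither reference gives what sharing adds to real differences. With 2 IRA arrays set against FO, MZ and T1 and the other 2 against Plasma and B1a, 146 or 104 genes were higher and 32 or 16 lower, depending on which 2. The genes higher in IRA cells were led by the disulfide enzyme gene Txndc11, at 8.63 in IRA cells against at most 7.24 elsewhere. Clptm1l (12.6), Kcnk6 (9.55), the thyroglobulin gene Tg (8.54), Pomt2 (7.80), Hid1 (8.64), Ostc (12.6), Srprb (10.8) and Sec61a1 (10.3) followed. Their next highest levels were 11.2, 8.25, 7.28, 6.56, 7.41, 11.5, 9.72 and 9.26. Hnrnpll, Olfml3, Cpeb3 and the agouti gene a were also higher, at 7.03, 6.20, 5.69 and 7.76. The receptor inhibitor gene Cd22 led the genes lower in IRA cells, at 6.42 against at least 7.90 elsewhere. H2-DMb1 (7.55), Cyb561a3 (6.56), Tlr1 (5.27), Tspan32 (6.46), Ltb (7.71), Acap1 (7.28), Tk2 (5.84) and Haao (6.31) were the lowest in IRA cells as well. Against FO, MZ and T1 alone, which share the set of arrays with IRA, 541 genes were higher and 552 lower in each comparison. The number lower in all 5 depended on individual arrays: it was 43 without IRA replicate 1, 51 without IRA replicate 3 and 166 without Plasma replicate 1, and it was 41 with median centring and 50 without a filter. Median centring left 344 genes lower against FO, MZ and T1.

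**Figure D4:**
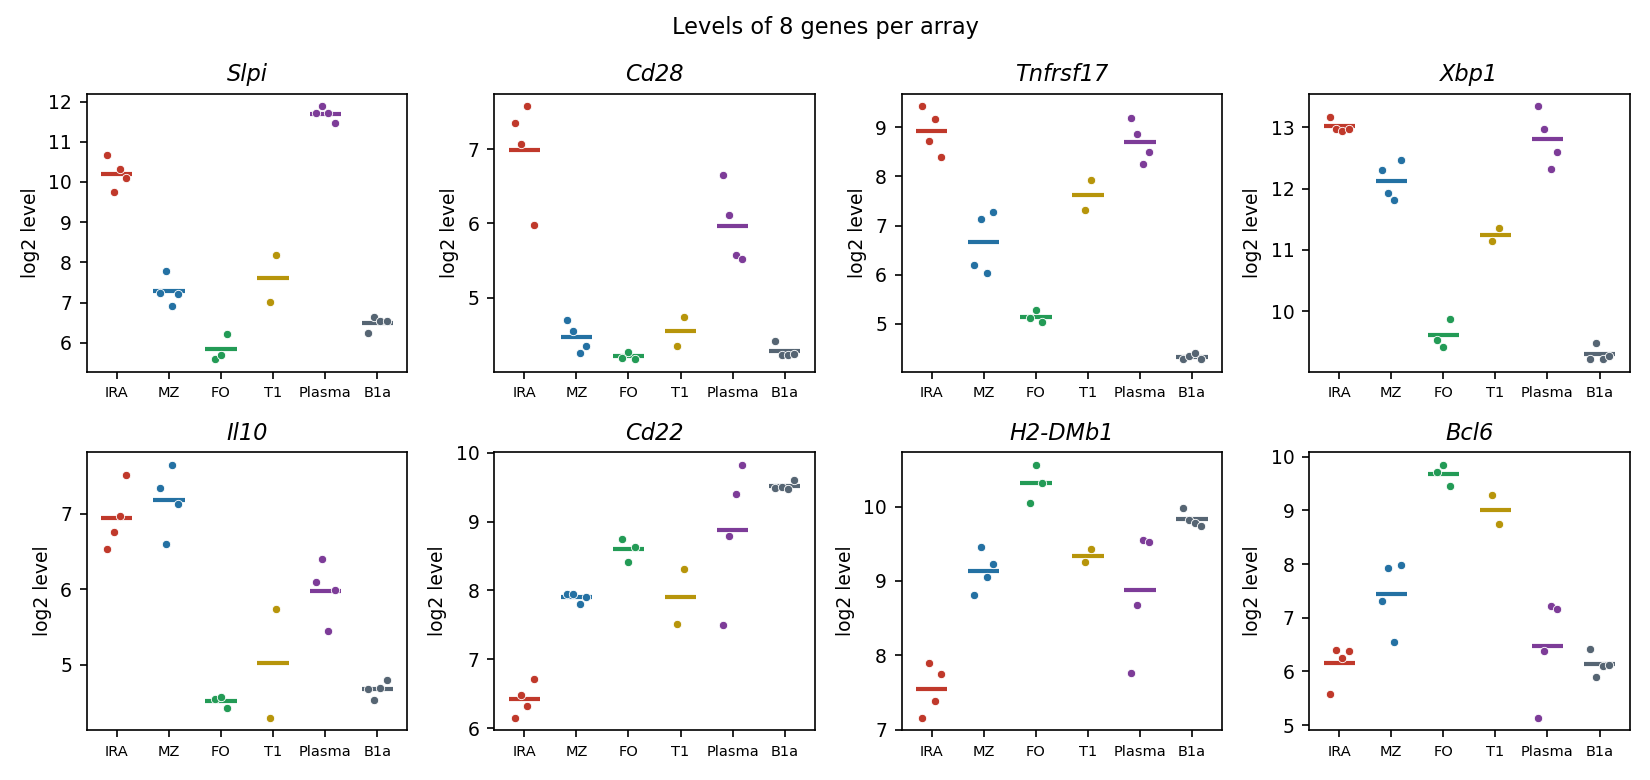
Log2 level of 8 genes on each array (points) by group, with the mean per group (bars across). Slpi lies at 10.21 in IRA and 7.30 in MZ cells, and Il10 at 6.95 and 7.18.

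MZ against FO cells asks how the 2 mature subsets of treated mice differed. Marginal zone, endoplasmic reticulum, antibody-secreting cell, mitosis and replication genes were higher in the MZ samples, and each of these list calls is lost with an estimated correlation (adjusted p = 0.183). Asb2 was 6.39-fold and Cd1d1 2.69-fold higher in MZ cells, and marginal zone genes were higher in 8 of 12 cases and 4 did not pass (adjusted p = 8.01e-07, and adjusted p = 0.183 with an estimated correlation). The largest rises were in Rsph1 (9.36-fold; 8.50 ± 0.34 against 5.28 ± 0.11), Bhlha15 (8.71-fold), Edem1 (8.04-fold), Derl3 (8.03-fold) and Plpp5 (7.99-fold). Il10 was at least 4.90-fold higher in MZ cells and Xbp1 5.74-fold. Scimp (5.55-fold), Zfp318 (5.45-fold), Bcl6 (4.68-fold) and Hvcn1 (4.56-fold) had the largest falls beside Fcer2a. Endoplasmic reticulum genes were higher in 23 of 34 cases (25 higher and 0 lower adjusted over the list alone; adjusted p = 4.62e-19, and adjusted p = 0.183 with an estimated correlation), antibody-secreting cell genes in 9 of 14 (10 higher and 0 lower adjusted over the list alone; adjusted p = 2.21e-09, and adjusted p = 0.183 with an estimated correlation), mitosis genes in 14 of 15 (adjusted p = 1.23e-17, and adjusted p = 0.183 with an estimated correlation) and DNA replication genes in 14 of 19 (16 higher and 0 lower adjusted over the list alone; adjusted p = 7.83e-10, and adjusted p = 0.183 with an estimated correlation). Respiratory chain genes were higher in 9 of 26 cases (11 higher and 0 lower adjusted over the list alone; adjusted p = 1.03e-05, and adjusted p = 0.188 with an estimated correlation) and B-1 cell genes in 5 of 13 (adjusted p = 0.00645, and adjusted p = 0.183 with an estimated correlation). Follicular genes were lower in 4 of 6 cases (0 higher and 5 lower adjusted over the list alone; adjusted p = 1.42e-05, and adjusted p = 0.195 with an estimated correlation), with Satb1 4.17-fold lower, and in 3 of 5 without Fcer2a (adjusted p = 0.000390, and adjusted p = 0.212 with an estimated correlation). B cell identity genes were lower in 6 and higher in 1 of 20 cases (1 higher and 7 lower adjusted over the list alone; adjusted p = 6.78e-04, and adjusted p = 0.513 with an estimated correlation), and MHC class II genes were lower in 4 of 15 (0 higher and 5 lower adjusted over the list alone; adjusted p = 0.0427, and adjusted p = 0.673 with an estimated correlation). The MHC class II call was lost without the sorting antigen genes H2-Aa and H2-Ab1 (adjusted p = 0.105) and without FO replicate 2, MZ replicate 3 or MZ replicate 4 (adjusted p = 0.103, 0.0582 and 0.134). Altogether 758 genes were higher and 641 lower, 291 and 124 of them at least 2-fold, without FO replicate 1 the number lower was 394, and median centring gave 490 higher and 284 lower.

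Plasma against FO cells was compared across the sets of arrays. Slpi rose 58.0-fold (11.69 ± 0.17 against 5.84 ± 0.33), Sec11c 39.8-fold, Prg2 34.8-fold, Oosp1 at least 23.1-fold, Ly6c1 26.1-fold and Sel1l 22.4-fold. Sorl1 (10.7-fold), Serpinb1a (9.36-fold) and Tbc1d10c (9.17-fold) fell most beside Fcer2a, and Ptpre (higher) and Tob2 (lower) had large differences that also separated the sets of arrays, as Sec11c and Oosp1 did. Endoplasmic reticulum genes were higher in 30, lower in 1 and not passing in 3 of 34 cases (adjusted p = 3.36e-14, and adjusted p = 0.183 with an estimated correlation). Antibody-secreting cell genes were higher in 11 and lower in 2 of 14 (adjusted p = 1.23e-05, and adjusted p = 0.247 with an estimated correlation), and mitosis genes were higher in 13 of 15 (adjusted p = 1.39e-05, and adjusted p = 0.356 with an estimated correlation). DNA replication genes were higher in 12 and lower in 1 of 19 (13 higher and 1 lower adjusted over the list alone; adjusted p = 6.17e-04, and adjusted p = 0.473 with an estimated correlation), respiratory chain genes higher in 19 and lower in 4 of 26 (adjusted p = 5.71e-05, and adjusted p = 0.207 with an estimated correlation), and B-1 cell genes higher in 8 of 13 (adjusted p = 0.00892, and adjusted p = 0.183 with an estimated correlation). B cell identity genes were lower in 12 and higher in 2 of 20 (adjusted p = 0.0170, and adjusted p = 0.662 with an estimated correlation), and follicular genes lower in 4 of 6 (adjusted p = 0.0243, and adjusted p = 0.520 with an estimated correlation), with Satb1 5.69-fold lower. The follicular call was lost without Fcer2a (adjusted p = 0.0795), and median centring ended the B-1, identity and follicular calls (adjusted p = 0.0572, 0.0726 and 0.0773). Altogether 2103 genes were higher and 2327 lower in Plasma than in FO cells, 1062 and 956 of them at least 2-fold, but 1564 and 3575 with median centring.

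Csf2, which encodes GM-CSF, was above background on none of the 21 arrays, with a smallest detection p of 0.129. Its receptor chain gene Csf2rb stood at 6.41 ± 0.51 in IRA, 6.18 ± 0.35 in MZ and 6.33 ± 0.18 in T1 cells, against 4.87 ± 0.06 in FO and 4.94 ± 0.33 in Plasma. Genes marking other cell types were measured beside the B cell genes. S100a8 stood at 9.68 ± 0.28 in FO, 8.77 ± 0.99 in MZ, 8.26 ± 0.84 in IRA and 6.05 ± 2.32 in T1 cells, and was above background on no B1a array. Lyz2 was brightest in B1a (8.83 ± 0.14), and C1qb in the second set of arrays, Plasma (6.33 ± 0.59) and B1a (5.90 ± 0.06). Mrc1 was at least 3.41-fold higher in IRA than in FO cells and stood at 6.66 ± 0.36. As lists, the markers of myeloid cells, of T and NK cells, and of red cell precursors and platelets passed in none of the 7 comparisons (lowest adjusted p 0.324, 0.57 and 0.212). The same held for adhesion and trafficking (lowest adjusted p 0.298), glycolysis (0.0682) and immediate early and heat shock genes (0.212). In IRA against FO, 6 of 13 glycolysis genes were higher (6 higher and 1 lower adjusted over the list alone), and 3 of 18 adhesion genes were higher and 7 lower. Lists of transitional B cell, dendritic cell, stromal and immunoglobulin genes had fewer than 5 measured members and were not tested. The list's median, mean and test differed in sign in 15 of the 147 tests, none of which passed, as for adhesion and trafficking in IRA against B1a (median 0.05, mean -0.46).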

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

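The rule applied in this part was set before the data were examined, and the genes it was applied to are those the report names. In each group of 4 arrays, the highest and the lowest array were compared with the nearest of the others, as the gap divided by the range of the group. Chance alone puts about 1 in 20 groups past the threshold. Of 474 sets of values 21 were past it, where 23.7 are due to chance: 17 of 377 gene levels, 3 of 84 list means, 1 of 5 similarities and 0 of 8 measures of the arrays. Their number is near that due to chance, and no explanation was tested. The rule finds only a lone array, so a graded spread over several arrays can escape it. Plasma replicate 1 was never past the threshold. Among 88 genes at least 4-fold higher in FO than in IRA, it was the lowest Plasma array in 83.

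Among the list means, immediate early and heat shock genes were high on IRA replicate 4 (7.82, next 6.59; gap 0.8758 of the range). Adhesion and trafficking genes were high on B1a replicate 1 (6.80, next 6.64; 0.9333), and markers of T and NK cells were low on MZ replicate 3 (next 5.24; 0.9449). IRA replicate 2, with the fewest detected probes in its group, had the lowest similarity to Plasma (0.888, next 0.916; 0.9189).

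For single genes in IRA arrays, the gaps were 0.9319 for Cd83 and 0.8885 for Ets1 (both low on replicate 1), 0.8415 for Xbp1 (high on replicate 1), 0.8474 for Cdc20, 0.8667 for Kif18b and 0.8852 for Uqcrb (all low on replicate 2), 0.9435 for Pou2af1 (high on replicate 3), and 0.8471 for Bhlha15 and 0.9086 for Ostc (both low on replicate 4). In MZ arrays they were 0.8481 for Socs2 (low on replicate 1), 0.8598 for Cd37 (high on replicate 2), 0.8317 for C1qb (high on replicate 3) and 0.8434 for Hid1 (high on replicate 4). In B1a arrays they were 0.8845 for Zcwpw1 (low on replicate 1), 0.8836 for Sec61a1 and 0.8356 for Xbp1 (both high on replicate 2) and 0.8549 for Sdc1 (high on replicate 3). Plasma arrays had none. FO, with 3 arrays, and T1, with 2, could not be looked at in this way.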

How the results depend on the processing

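The alternatives were set before the data were examined, except 5 chosen after seeing the data: the 13 arrays of IRA, FO, MZ and T1 alone, the fit without the 3 arrays that detect under 7000 probes (IRA replicate 2, MZ replicate 3 and T1 replicate 1), IRA against FO, MZ and T1 in place of all 5, the fit without Plasma replicates 3 and 4, and the lists without genes of sorting antigens. A slide as a block could not be run, since the files name no slide. MZ was the group nearest to IRA in all 29 alternatives computed for similarity, none of which removed the difference between the sets of arrays. Of 893 results for named genes, 123 lost their call or reversed under at least 1 alternative, and 61 of 147 list results did. Both totals include results that had no call to lose. The 61 were all the list calls there were, since each was lost with the estimated correlation between genes.

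For gene lists, the estimated correlation between genes changed most, as it ended every call. For counts of genes, median centring in place of quantile normalisation changed most. It moved the median of all genes by -0.21 in IRA minus FO, -0.25 in IRA minus T1, 0.22 in IRA minus Plasma, 0.37 in IRA minus B1a and -0.37 in Plasma minus FO, and by less than 0.1 in the other 2 comparisons. Genes higher became 3651 in IRA minus B1a (66.1% of those called, from 49.4%), those in IRA minus Plasma 2683 with 1127 lower (from 1921 and 1507), and 30.4% of called genes were higher in Plasma minus FO (from 47.5%, with 3575 lower). In IRA minus MZ 752 were higher and 514 lower (59.4% higher, from 50.1%). Counts fell to 490 higher and 284 lower in MZ minus FO, 41 lower in IRA against all 5 and 344 lower in IRA against FO, MZ and T1, and similarity to B1a was 0.7911. It reversed Pcna in IRA minus MZ (-0.025853), Cxcr3 (-0.038177) and Ier2 (-0.29497) in IRA minus T1, Spn in IRA minus B1a (0.63144), and Cd5 (-0.88922), Cd8b1 (-0.21287), Il5ra (-0.089603) and Spn (-0.42098) in Plasma minus FO. Of these, Spn in IRA minus B1a and Cd5 in Plasma minus FO passed in the new direction (adjusted p 0.0235 and 0.00239). The cause was not tested.

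Similarity moved with the filter. Without one it was 0.92689 to FO, 0.96552 to MZ, 0.92947 to T1, 0.9439 to Plasma and 0.88975 to B1a, and 50 genes were lower in all 5. With detection on at least 4 arrays it was 0.8768 to FO and 0.79038 to B1a, and with detection on every array of a group 0.86997 to FO, 0.88834 to T1, 0.89393 to Plasma and 0.7732 to B1a. The authors' values gave 0.94457 to MZ, 0.89205 to T1 and 0.8022 to B1a. Array weights left 891 genes lower in IRA minus T1 (1388 without weights). The cause of these was not tested.

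Single arrays moved some counts. Without 1 array, genes higher in IRA minus T1 ranged from 897 (without T1 replicate 1) to 1502, and similarity to T1 from 0.8857 to 0.91573, where T1 ranked 2 of 5 without its replicate 1 and 4 of 5 without its replicate 2. The lone T1 array is then assumed to vary like the other groups. Cd5 in IRA minus T1 ranged from -1.3563 to 0.10499. Genes lower in MZ minus FO ranged from 394 (without FO replicate 1) to 665, and genes lower in all 5 from 43 (without IRA replicate 1; 51 without IRA replicate 3) to 166 (without Plasma replicate 1). Without the 3 arrays of under 7000 probes, 955 genes were higher in IRA minus T1 and 50 lower in all 5. The cause was not tested. All other counts of genes stayed within 1.5 times the main count in each alternative run.

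Replicate number as a block, which stands for a pairing the numbers do not show, gave 719 higher and 740 lower in IRA minus MZ. The 13 arrays alone gave 1444 and 1523 in IRA minus FO, 685 and 715 in IRA minus MZ and 1252 and 1298 in IRA minus T1. Each pair fitted alone gave 1086 and 1028 in IRA minus T1. Without Plasma replicates 3 and 4, IRA minus Plasma gave 1444 and 1182. Lists without genes of sorting antigens lost 2 calls, MHC class II in MZ minus FO (adjusted p = 0.105) and follicular in Plasma minus FO (adjusted p = 0.0795).

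Signal over background limits what can be said of faint transcripts. Csf2, Itga4 and others near background cannot be ranked between groups, and a bound of at least N-fold can hide a larger difference. T1 replicate 1 detected 5622 probes, so a gene absent there may be below its reach (897 genes higher in IRA minus T1 without T1 replicate 1).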

Other observations

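Genes in this and the next paragraph were chosen after their values were seen. The mean over the antibody-secreting cell genes was 8.96 ± 0.19 in IRA, 8.65 ± 0.39 in Plasma, 7.81 ± 0.16 in MZ, 7.40 ± 0.35 in T1 and 6.60 ± 0.06 in FO cells, with 6.62 ± 0.01 in peritoneal B1a cells. Isg20, grouped with interferon-stimulated genes, stood at 8.22 ± 0.48 in Plasma (across the sets of arrays), 6.63 ± 0.26 in IRA, 5.76 ± 0.25 in MZ and near background in T1, FO and B1a. The mean over the mitosis genes was 5.94 ± 0.09 in T1 and 5.94 ± 0.16 in FO cells.

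Csf2rb2 was above background on all 4 B1a arrays (5.35 ± 0.16) and on none of the other 17. Il5ra was 6.93 ± 0.24 in B1a and 5.29 ± 0.16 in Plasma, and was above background on at most 1 array in each other group. Vpreb3, a partner of immature receptors, was highest in T1 (11.15 ± 0.27), between 9.17 and 9.88 in the other splenic groups and above background on no B1a array. Hba-a1, a red cell globin, was 10.12 ± 1.41 in B1a against 6.81 ± 0.36 in IRA cells, with a wide spread between arrays.

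In the tests below, those of other cells in the MZ sort were chosen after the results were seen, and those of the sets of arrays and of other splits were set before. The first concerns the sets of arrays. In 123 genes (122 higher, 1 lower) all 8 Plasma and B1a arrays lay at least 1 log2 outside all 13 others, against at most 15 for any other of the 15 ways to take 2 groups (FO with B1a). The differences of IRA minus Plasma and MZ minus B1a, which share no array, correlated at 0.6841 across genes, and IRA minus Plasma with FO minus B1a at 0.647. IRA minus B1a correlated at 0.380 with MZ minus FO, which does not cross the sets, so a value over the bound of 0.3 arises without them as well, and at -0.0971 with Plasma minus FO. A difference in how the 2 sets were made or read could give both values. A programme that splenic plasma cells and resting peritoneal cells share stays open as well, since no group was measured in both sets.

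The second concerns the secretory and mitosis transcripts of MZ cells. IRA cells in the MZ sort could bring them, although the gates differ in CD93. To explain the endoplasmic reticulum genes, IRA RNA would need to be 38.4% of the MZ sample. The other 138 genes at least 4-fold higher in IRA than in FO needed a median of 37.7% (quartiles 29.4% and 49.97%). Of these, 7.25% (10 genes) needed less than 0.5 of that share, between the bounds set for and against it. In limma's test of levels below what that share brings, 1 gene passed, Slpi, with an MZ level of 13.3% of IRA (adjusted p = 0.00446), where more than 5 would have argued against it. The bound of 5 genes was set after the results were seen, and that share by itself would put Slpi above its MZ level. The test therefore does not show that 1 share holds for all genes. For Plasma cells, 29.3% of 82 genes needed less than 0.5 of the share of 32.9%, with a 95% interval of 19.7% to 40.4%, which decides nothing. Single genes needed Plasma shares from 3.15% (Slpi) and 6.74% (Jchain) to 73.0% (Derl3) and 83.5% (Edem1). IRA shares of picked genes ran from 3.13% (Cd28), 8.91% (Slpi), 13.2% (Prdm1), 15.6% (Tnfrsf17) and 17.6% (Jchain) to 40.2% (Derl3) and 50.04% (Xbp1), with Cd28 and Prdm1 near background in MZ. These genes do not mark the upper end. Il10, also at least 4-fold higher in IRA than in FO, ran from 6.60 to 7.65 in MZ and from 6.54 to 7.52 in IRA cells. A share of 38.4% would not bring that MZ level, but 1 gene does not decide for the set. The test of Plasma cells left out genes at least 2-fold higher in B1a than in FO, since Plasma and B1a share a set of arrays, a change made after a first form with all 271 genes gave 66.4%. So for the secretory genes IRA or plasma cells in the sort and secretory MZ cells cannot be told apart.

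The mitosis genes higher in MZ than in FO were tested apart from these. The 14 genes needed a median Plasma share of 146%, with Top2a at 194%, and a lower limit of 58.0% over the 4 MZ arrays. Plasma RNA at that limit alone would bring 74 genes above their MZ level, among them Slpi and Jchain, where more than 5 were set to argue against it (genes at least 2-fold higher in B1a than in FO again aside). This argues against Plasma cells in the sort as the whole cause of the mitosis part, although the comparison crosses the sets of arrays. The IRA share they needed was 65.0% with a lower limit of 38.1%, at which 1 gene, Slpi, would exceed its MZ level. All 4 MZ arrays, at 43.3% to 83.7%, and all 14 genes, at 43.4% (Bub1b) to 89.3% (Kif23), lay above the 38.4% that the endoplasmic reticulum genes needed. The spread between the 4 arrays is wide, however, and the lower limit of 38.1% does not exceed that 38.4%. So IRA cells in the sort as the whole cause and cycling MZ cells cannot be told apart. A first form took the lower limit over genes, which are not independent, and gave 101 genes for Plasma and 6 for IRA. MZ cells activated by LPS stay untested for both parts, as no untreated MZ cells were measured.

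The Plasma arrays were unlike in B cell genes. The mean of 88 genes at least 4-fold higher in FO than in IRA was 6.31 on Plasma replicate 1, 7.10 on replicate 2, and 7.81 and 7.84 on replicates 3 and 4. The antibody-secreting cell genes went the other way, with 9.10 on replicate 1 and 8.30 on replicate 4. Without replicate 1 the genes lower in all 5 comparisons were 166 in place of 79. The reason was not tested.

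Other splits of the same arrays were run for each comparison of at least 3 arrays a side. Of the 35 splits, only 1, the real one, gave as many genes in each of the 6 comparisons. The test cannot reach fewer than 1 of 35, and the 6 comparisons share arrays and were not adjusted together. Chance is therefore unlikely for each comparison taken alone, but is not excluded for all 6 together. In IRA with Plasma, IRA with B1a and Plasma with FO the real split is also the one between the sets of arrays. The real and the highest other counts were 3219 and 2215 for IRA with FO, 1522 and 7 for IRA with MZ, 3428 and 381 for IRA with Plasma, 4639 and 0 for IRA with B1a, 1399 and 874 for MZ with FO, and 4430 and 3371 for Plasma with FO. The high other counts with FO came from splits that left 3 arrays of the larger group on 1 side and put the 3 FO arrays with the remaining one on the other, so they keep most of the real grouping. IRA with T1 was not run in this way, since T1 held 2 arrays.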
